A study of Arabidopsis thaliana with 30 samples.

How the data were processed

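Rosettes of 3-week-old Arabidopsis thaliana plants were compared between the wild type Col-0 and the mutant yda11, named for YODA, a MAP kinase kinase kinase known for its part in stomatal patterning. Per the labels, plants grew under a 10 h day at 22 °C. Pots of 9 plants were sprayed with 0.6 ml of a spore suspension of Plectosphaerella cucumerina BMM, a necrotrophic fungus, or with water as mock treatment. They were then moved to a chamber at 24 °C by day. Rosettes were collected before treatment (time zero) and at 1 and 3 days post inoculation (dpi). Total RNA was labelled with biotin and hybridised to a 1-colour expression array, 1 array per sample. The design gives 10 groups of 3 arrays, 30 arrays in all, and the labels give 3 independent experiments without saying that a replicate number stands for an experiment.

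The deposited values are intensities, 1 linear signal per probe set and array. Their quartiles lay close together over the arrays, so they had been normalized between arrays, by a method not given in the sources used here. The median intensity per array ran from 48.2 to 56.5. The probe sets for bacterial control transcripts had median intensities from 6.07 to 11.9, which is the background that limits dim probe sets. The number of arrays limits the precision of every value.

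Values were put on the log2 scale before any test. Of 22810 probe sets, the 64 AFFX controls were left out and 22746 were tested without a filter on intensity. The probe set annotation used here matched 13513 of the tested probe sets to 1 gene and 503 to several genes. The other 8730 have no name and are counted but not described. YODA itself was not matched to a probe set and is not analysed here.

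A linear model with 1 mean per group was fitted over all 30 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 20 residual and 4.03 prior degrees of freedom. The tests are two-sided, and the Benjamini-Hochberg adjustment ran over the 22746 probe sets of each comparison. A probe set counted as changed at an adjusted p under 0.05. Differences are log2 fold changes with their standard error (SE). The 15 comparisons were infected against mock plants of each genotype and day, yda11 against wild type in each of the 5 conditions, the difference between the genotypes in infection response at each day, the difference between the days in each genotype, and mock-treated plants at each day against time zero over both genotypes. A further comparison, yda11 against wild type averaged over the 5 conditions, was chosen after the values were seen.

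The comparisons, the tests, 26 gene lists, the alternatives and the rule for named genes were set before the data were examined. In each comparison the rule takes the changed probe sets that match 1 gene and whose arrays do not overlap between the groups, and names up to 10 with the highest and up to 10 with the lowest log2 fold change, or up to 5 each way for the differences and the comparison with time zero. It adds up to 4 members of each list with the smallest adjusted p and, where fewer than 5 probe sets pass, those with the smallest p. The condition on overlap was dropped for differences of responses and for averages over genotypes. Any other gene named here was chosen after its values were seen.

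Of the 519 genes in the 26 lists, 82 were measured by a probe set matched to 1 gene, and each gene was represented by its probe set with the highest mean. The 12 lists with 3 or more measured members were tested with camera, with an inter-gene correlation preset at 0.01, and adjusted over 180 tests. A further 13 lists had 1 or 2 measured members and 1 list had 0, so these were not tested as sets. Because coverage was thin, 29 gene families were added after the probe set annotation and the first lines of values had been seen, but before any fold change, and adjusted over 435 tests of their own. The counts include 1 family whose results are not reported here. Of the 36 calls among the first lists, 10 held when camera estimated the correlation from the data. Of the 82 calls among the added families, 0 held, while fry, which asks only whether the members move on balance in 1 direction, made 132 calls.

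The model was tested on simulated arrays, drawn from group means of these data with independent noise of the fitted spread and known differences added. For yda11 against wild type after infection at 3 dpi it called 34.3% of the differences of log2 0.5 and 88.7% of those of log2 1, with 10 false calls among 159. For the difference in infection response at 3 dpi these shares were 5.06% and 74.5%, with 3 false calls among 113. The simulated arrays hold no array that stands apart and no correlation between genes or replicate numbers, so the shares do not allow for these.

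The alternatives were the replicate number as a block, a fit to the arrays of each comparison alone, dim probe sets left out, quantile normalization, median centring, a variance trend with robust settings, array weights, a minimum change of 2-fold, 1 probe set per gene, and each array left out in turn. List tests were repeated with an estimated correlation and with fry. Leaving out the 3 arrays that stood apart from the rest was added after the values were seen.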

Results

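Transcript levels were measured in 30 rosette samples, with 3 arrays for each of 10 groups: wild type and yda11 at time zero, after mock treatment at 1 and 3 dpi, and after inoculation with the fungus at 1 and 3 dpi. Infected and mock-treated arrays lay on opposite sides of the first principal component, which held 62.3% of the variance over the arrays. The second component, with 10.1%, set time zero apart from the mock-treated plants. None of the 435 pairs of arrays held identical values throughout, and the highest share of identical values in a pair was 1.26%. A few arrays stood apart. In yda11 at time zero, replicate 2 had a bacterial control median of 11.9 against a median of 6.62 over all arrays, and its mean correlation with its own group was 0.979. In wild type after mock treatment at 1 dpi, the plastid-encoded genes of replicate 3 had a median log2 intensity of 8.84 against 10.49 and 11.13 on the other arrays of the group.

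**Figure D1:**
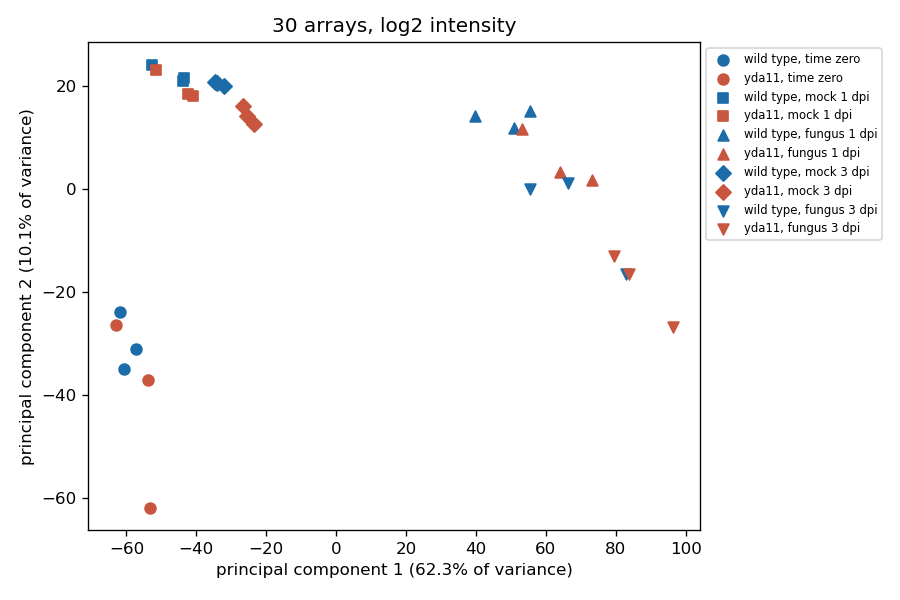
The 30 arrays on the first and second principal components of the log2 intensities, coloured by genotype, with a marker shape for each condition. The fungus-inoculated arrays lie right of 0 on the first component (62.3% of the variance) and the mock-treated and time-zero arrays left of it.

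The question of the first comparisons was how rosettes of each genotype respond to the fungus. In wild type at 1 dpi, AT1G26380, a berberine bridge enzyme-like oxidase, rose 90.8-fold over mock (log2 6.50 ± 0.33 SE, n = 3 per group, adjusted p = 1.4e-13). The related oxidases AT1G26390 and AT1G26420 rose by 5.73 ± 0.31 and 5.64 ± 0.31 on the log2 scale, and the class III peroxidase Prx37 (AT4G08770) by 6.35 ± 0.27. Both jasmonate- and ethylene-responsive plant defensins rose, PDF1.2 (AT5G44420) by 5.81 ± 0.72 (SD 1.10 over the mock arrays) and PDF1.2b (AT2G26020) by 5.93 ± 0.94 (SD 1.98). So did UGT76B1 (AT3G11340), a glucosyltransferase of immune metabolites, by 5.93 ± 0.33, the chitinase CHI (AT2G43570) by 5.37 ± 0.26, AT5G38900 by 5.41 ± 0.17 and AT4G16260 by 5.36 ± 0.40. On the other side, AT1G62510 fell by 3.41 ± 0.38, the cold-regulated gene COR15A (AT2G42540) by 3.21 ± 0.25 and the expansin-like gene EXLA1 (AT3G45970) by 2.94 ± 0.42. Also lower were AT3G53250 at -2.89 ± 0.49, AT3G15720 at -2.82 ± 0.32, AT4G25780 at -2.73 ± 0.23, AT4G16563 at -2.57 ± 0.38, AT1G51090 at -2.48 ± 0.31, the nitrate transporter gene AT3G21670 at -2.43 ± 0.29 and AT5G03120 at -2.41 ± 0.27. In infected plants AT3G15720 lay at intensity 6.38, under the bacterial control median of 6.62, so its fall is a lower bound. In all, 6859 of 22746 probe sets changed, 2628 higher and 4231 lower, and 1893 of them at least 2-fold.

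At 3 dpi, 6943 probe sets had changed in wild type, 3127 higher and 3816 lower, and 2024 at least 2-fold. The osmotin gene OSM34 (AT4G11650) rose 183-fold (log2 7.52 ± 0.42, adjusted p = 1.1e-12), ahead of AT1G26390 at 7.35 ± 0.31, Prx37 at 6.89 ± 0.27, CHI at 6.59 ± 0.26 and PDF1.2 at 6.18 ± 0.72. JRG21 (AT3G55970), a jasmonate-induced oxygenase, rose by 5.20 ± 0.24, AT1G68620 by 6.15 ± 0.28, AT1G26380 by 5.46 ± 0.33, AT4G37290 by 5.19 ± 0.24 and the chitinase-like gene AT2G43590 by 5.14 ± 0.29. The largest falls among the named genes were those of AT1G62510 (-3.47 ± 0.38), AT4G25780 (-3.00 ± 0.23), COR15A (-2.87 ± 0.25), AT3G53250 (-2.77 ± 0.49) and COR15B (AT2G42530, -2.68 ± 0.26). AT5G57760 (-2.57 ± 0.58), AT1G69523 (-2.54 ± 0.20), AT1G13650 (-2.49 ± 0.35), AT3G21670 (-2.39 ± 0.29) and the iron-status peptide gene AT1G47400 (-2.37 ± 0.31) fell as well.

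In yda11 at 1 dpi, 7214 probe sets changed, 3046 higher and 4168 lower, with 2275 at least 2-fold. Prx37 rose 137-fold (7.10 ± 0.27, adjusted p = 3.7e-16), and AT1G26380 and AT1G26390 rose by 6.93 ± 0.33 and 6.93 ± 0.31. PDF1.2b rose by 6.87 ± 0.94 (SD 1.58 over the mock arrays), PDF1.2 by 6.72 ± 0.72 (SD 1.20), UGT76B1 by 6.65 ± 0.33, AT3G18250 by 6.37 ± 0.33, CHI by 6.14 ± 0.26, AT4G39670 by 6.14 ± 0.21 and AT5G38900 by 6.01 ± 0.17. EXLA1 fell by 3.62 ± 0.42, AT1G62510 by 3.57 ± 0.38, AT3G53250 by 3.41 ± 0.49 and COR15A by 3.37 ± 0.25. The iron-deficiency regulator BHLH101 (AT5G04150) fell by 2.78 ± 0.60, next to AT4G25780 (-2.94 ± 0.23), AT3G21670 (-2.90 ± 0.29), AT3G15720 (-2.86 ± 0.32), AT1G51090 (-2.69 ± 0.31) and AT5G03120 (-2.69 ± 0.27). The changes of AT4G39670, at intensity 5.33 in mock-treated plants, and AT3G15720, at 6.36 in infected plants, are lower bounds, since these lie under the bacterial control median of 6.62. CHI at 6.92 and UGT76B1 at 7.10 in mock-treated plants lie close to it.

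By 3 dpi in yda11, AT1G26390 was up 314-fold (8.29 ± 0.31, adjusted p = 3.1e-16) and OSM34 276-fold (8.11 ± 0.42). CHI rose by 6.58 ± 0.26, AT1G68620 by 6.47 ± 0.28, PDF1.2 by 6.41 ± 0.72, Prx37 by 6.39 ± 0.27, JRG21 by 5.45 ± 0.24 and AT4G16260 by 5.43 ± 0.40. AT3G13610, the feruloyl-CoA hydroxylase of scopoletin synthesis, rose by 5.54 ± 0.20 and the peroxidase PRX52 (AT5G05340) by 5.46 ± 0.28. AT3G53250 fell by 3.65 ± 0.49, AT1G62510 by 3.60 ± 0.38, AT5G57760 by 3.43 ± 0.58 and COR15A by 3.00 ± 0.25, with AT4G25780 (-2.97 ± 0.23), AT1G69523 (-2.87 ± 0.20), AT4G36700 (-2.78 ± 0.28), AT1G47400 (-2.66 ± 0.31), AT5G01790 (-2.62 ± 0.36) and AT5G05890 (-2.53 ± 0.19) behind them. The changes of AT3G13610 and PRX52, at intensities 5.80 and 6.50 in mock-treated plants, and of AT4G36700, at 5.35 in infected plants, are lower bounds, as these lie under the bacterial control median of 6.62. The count was 7729 changed probe sets, 3218 higher and 4511 lower, and 2538 at least 2-fold. All 20 genes named for each of these 4 infection comparisons kept their call without each array in turn and in the fit to the 6 arrays of the comparison. The labels state covered trays at high humidity for inoculated plants and do not say so of mock-treated plants.

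**Figure D2:**
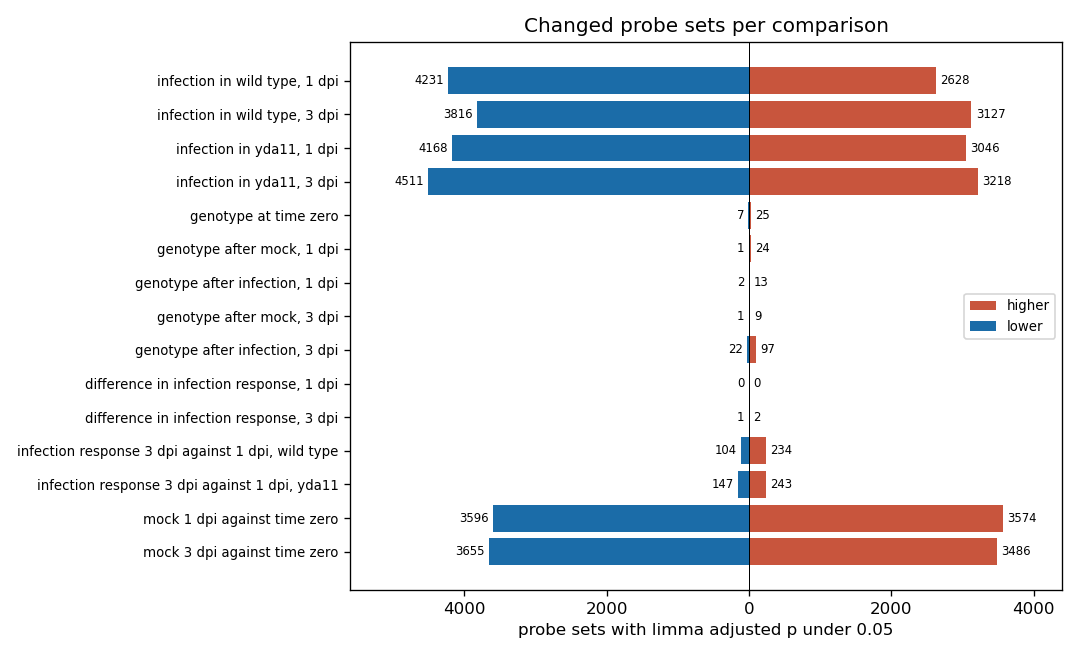
Number of probe sets that changed (adjusted p under 0.05 by limma, of 22746 tested) in each comparison, higher to the right and lower to the left of 0. The infection comparisons hold 6859 to 7729 probe sets and the comparisons of yda11 with wild type within a condition 10 to 119.

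Secreted antimicrobial proteins, such as chitinases, osmotin, thionins and defensins, rose as a group after infection. Of the 14 measured members in wild type at 1 dpi, 8 rose and 2 fell over all probe sets (8 and 4 adjusted over the list alone), with camera adjusted p = 0.00131 and adjusted p = 0.0374 with an estimated correlation. At 3 dpi, 8 rose and 2 fell (8 and 4 adjusted over the list alone, camera adjusted p = 0.000122). Counts in yda11 were 7 up and 3 down at 1 dpi (camera adjusted p = 0.00122) and 8 up and 3 down at 3 dpi (0.000759), each 8 and 4 adjusted over the list alone. Among them, AT4G01700 rose by 3.51 in wild type and 4.19 in yda11 at 1 dpi, PDF1.4 by 4.29 in wild type at 3 dpi and THI2.1 by 3.86 in yda11 at 3 dpi. The 3 measured genes of tryptophan-derived defence metabolism rose in both genotypes on both days, also when adjusted over the list alone (camera adjusted p = 5.7e-06 to 0.000248). They are AT2G04400, an indole glycerol phosphate synthase, which rose by 2.80 in wild type at 1 dpi, CYP71B6, by 2.32, and the glucosinolate enzyme UGT74B1, by 1.17. The calls of these 2 lists in the 4 infection comparisons held with an estimated correlation (adjusted p = 0.0252 to 0.0374).

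All 7 measured genes of pattern-triggered immunity rose in each infection comparison, also when adjusted over the list alone. In wild type at 1 dpi these were WRKY53 by 2.91, PUB23 by 2.91, WRKY6 by 2.38, WRKY22 by 1.95, the receptor gene EFR by 1.57, its signalling kinase BIK1 by 1.40 and PUB22 by 0.99. The list's camera adjusted p was 9.3e-07 in wild type and in yda11 at 1 dpi, 9.9e-07 in wild type and 4.4e-07 in yda11 at 3 dpi, and its adjusted p = 0.102 to 0.108 with an estimated correlation. Of the ethylene response list, whose 3 measured genes are all defensins, 3 rose at 1 dpi and 2 at 3 dpi in either genotype. Adjusted over the list alone these were 3 at 1 dpi, 2 in wild type at 3 dpi and 3 in yda11 at 3 dpi (camera adjusted p = 0.00201, 0.0275, 0.00552 and 0.0206 in wild type at 1 and 3 dpi and yda11 at 1 and 3 dpi, and adjusted p = 0.129 to 0.304 with an estimated correlation). The salicylic acid list had 2 measured genes, too few for a set test. GRX480, a glutaredoxin induced by salicylic acid, rose by 2.96 and 3.77 in wild type and by 3.37 and 4.90 in yda11 at 1 and 3 dpi, and SAG101 by 0.45, 0.90, 1.07 and 1.45 in the same order.

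Of 4 measured genes of abscisic acid response, 3 fell in each infection comparison, also when adjusted over the list alone: COR15A, COR15B and COR47. COR47 fell by 2.20 in wild type at 1 dpi, and in yda11 it fell by 2.32. Camera adjusted p was 0.00193 and 0.00629 in wild type and 0.00253 and 0.00531 in yda11, with adjusted p = 0.108 to 0.148 with an estimated correlation. Of 10 measured nuclear photosynthesis genes, 6 fell and 1 rose in wild type at 1 dpi, also over the list alone, where the list did not pass (camera adjusted p = 0.132). At 3 dpi 8 fell and 1 rose in wild type (9 and 1 adjusted over the list alone, camera adjusted p = 0.0160), and 9 fell and 1 rose in yda11 at 3 dpi (9 and 1 adjusted over the list alone, 0.00632). Their adjusted p was 0.424 and 0.331 with an estimated correlation. In yda11 at 1 dpi, 6 fell and 1 rose, also over the list alone (camera adjusted p = 0.0442, adjusted p = 0.484 with an estimated correlation, 0.0752 under quantile normalization and 0.0913 without dim probe sets). SBPASE, a Calvin cycle enzyme, fell by 0.60 and 0.74 and PSAN of photosystem I by 0.68 and 0.81 in wild type and yda11, while LHCB4.3 rose by 1.41 in both. STOMAGEN, which encodes a peptide that promotes stomatal formation, fell by 1.53 and 1.02 in wild type and by 1.56 and 1.26 in yda11 at 1 and 3 dpi. Its list of stomatal lineage genes, with 4 measured, passed in neither genotype (camera adjusted p = 0.179 to 0.381).

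Several of the added families moved together after infection, although their camera calls did not hold with an estimated correlation. Tubulins fell, with 6 of 7 members lower in each infection comparison. Examples are TUB1 by 1.40, TUB5 by 1.19 and TUB6 by 1.18 in wild type at 1 dpi (camera adjusted p = 0.000702, and adjusted p = 0.291 with an estimated correlation). Of 14 genes of endoplasmic reticulum protein folding, 9 rose in wild type and 12 in yda11 at 1 dpi, among them the stress regulator BZIP60 by 1.62 and 1.59 (camera adjusted p = 7.7e-06 and 5.9e-06, and adjusted p = 0.159 with an estimated correlation in both). Chlorophyll biosynthesis genes fell at 3 dpi, 7 of 8 in wild type and 7 of 8 in yda11, such as CHLI2 by 1.16 and 1.33 (camera adjusted p = 0.00118 and 0.00425, and adjusted p = 0.320 and 0.382 with an estimated correlation). Of 18 expansins, 8 fell at 1 dpi in either genotype (camera adjusted p = 0.0137 and 0.0301, and adjusted p = 0.291 with an estimated correlation in both). EXPA8 fell by 2.18 in wild type and 2.62 in yda11. The list of expansins and xyloglucan endotransglucosylases set before the data were examined did not pass at 1 dpi, with 2 of 5 lower in wild type and 1 of 5 in yda11, the same adjusted over the list alone (camera adjusted p = 0.39 and 0.498). Of 70 TIR-domain resistance genes, 16 passed as higher in wild type and 23 in yda11 at 1 dpi, and most did not, with AT1G57630 at 4.40 and 4.91 (camera adjusted p = 0.000261 and 0.000825, and adjusted p = 0.340 and 0.402 with an estimated correlation). Over all 22746 probe sets, 2628 and 3046 were higher.

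Wild type and yda11 shared most of the response. At 1 dpi, 2347 probe sets were higher in both genotypes, where 351.9 would be shared if the calls were independent, and 3332 were lower in both, where 775.3 would be. At 3 dpi these counts were 2710 and 3295, against 442.4 and 756.8. Opposite changes numbered 0 at 1 dpi and 2 at 3 dpi. Over all probe sets, which are not independent replicates, the log2 fold changes of the genotypes correlated at r = 0.946 at 1 dpi and 0.957 at 3 dpi. The slope of yda11 on wild type over the probe sets changed in either genotype was 1.09 and 1.08. Probe sets called in yda11 alone enter this slope, and their selection can raise it.

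How the response differs between the days was tested in each genotype. JRG21 responded more at 3 dpi than at 1 dpi, by 5.06 ± 0.35 on the log2 scale in wild type (adjusted p = 4.0e-09) and by 4.56 ± 0.35 in yda11 (1.9e-08), and OSM34 by 4.69 ± 0.60 and 4.47 ± 0.60. AT3G55790 and AT5G39520 also responded more at 3 dpi in both genotypes, AT2G37750 in wild type (3.39 ± 0.52) and AT1G09500 in yda11 (4.03 ± 0.49). In yda11 the chitinase-like gene AT2G43620 responded less at 3 dpi by -3.84 ± 0.42, AT4G36700 by -2.30 ± 0.39, UGT76B1 by -2.26 ± 0.47, AT1G56060 by -2.11 ± 0.33 and AT5G48540 by -1.93 ± 0.28. AT2G43620 led the genes named as higher in mock-treated plants at 3 dpi against time zero, and was not among those named at 1 dpi. A raised mock level at 3 dpi therefore enters its difference, which is no measure of the level in infected plants. AT3G55790, AT5G39520, AT1G09500 and AT4G36700 lay under the bacterial control median of 6.62 in at least 1 of the groups compared, so background limits the size of their differences. The 5 lowest differences in wild type were plastid-encoded: psaA (-4.73 ± 1.12), psbC (-3.36 ± 0.66), ycf4 (-3.33 ± 0.59), atpH (-2.94 ± 0.49) and atpI (-2.94 ± 0.65). Without the 3 arrays that stood apart, among them the wild-type mock array picked for its low plastid values, psaA was at -3.50 (adjusted p = 0.192) and atpI at -2.18 (adjusted p = 0.131). In the fit to the arrays of the comparison alone, which leaves the differences the same by construction, psaA, psbC and atpI did not pass (adjusted p = 0.0604, 0.116 and 0.0675). In all, 338 probe sets differed in wild type, 234 of them higher at 3 dpi, and 390 in yda11, 243 of them higher. With array weights the counts were 933 and 722. The share higher in wild type, 69.2%, was 47.6% under median centring.

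**Figure D3:**
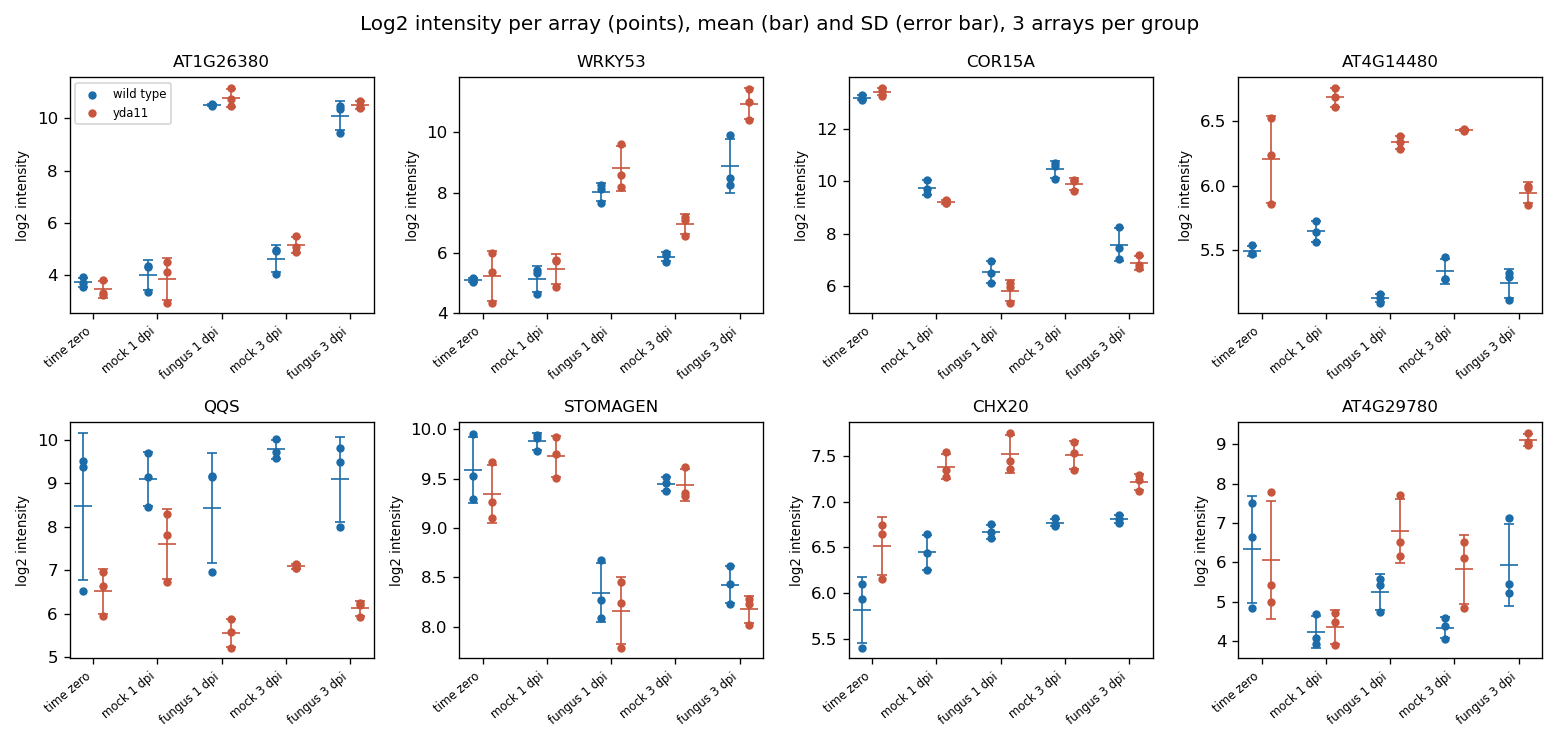
Log2 intensity of 8 genes in each group, with points for the 3 arrays, a bar for the mean and error bars for the SD. AT1G26380 and WRKY53 are higher and COR15A and STOMAGEN lower after inoculation in both genotypes, AT4G14480 and CHX20 have higher and QQS lower means in yda11 in every condition, and AT4G29780 has its highest mean in infected yda11 at 3 dpi.

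The mutant was compared with wild type within each condition, to find what differs before and after infection. At time zero, AT1G23200 was 2.39-fold higher in yda11 (log2 1.25 ± 0.13, n = 3 per group, adjusted p = 2.1e-05), AT2G39690 was higher by 1.31 ± 0.26 and AT1G68500 by 1.05 ± 0.14. AT5G25840 (0.97 ± 0.15), AT1G33811 (0.85 ± 0.14), AT3G20300 (0.79 ± 0.12), AT2G19980 (0.76 ± 0.15), AT4G35070 (0.75 ± 0.16), AT4G14480 (0.71 ± 0.11) and AT1G56380 (0.69 ± 0.14) were higher, and AT3G53220 (-1.15 ± 0.20) and AT1G71690 (-0.43 ± 0.08) lower. AT1G71690 lay at intensities 5.16 and 6.97, about the bacterial control median of 6.62, so its difference is not shown above background. There were 32 changed probe sets, 25 higher and 7 lower in yda11. Of the 12 named genes, 5 kept their call without each array in turn (AT1G23200, AT1G68500, AT5G25840, AT3G20300 and AT4G14480). The yda11 group holds replicate 2, the array of raised background. Without the 3 arrays that stood apart, which include it, the count was 41. AT2G39690 (0.94, adjusted p = 0.138), AT4G35070 (0.70, adjusted p = 0.173) and AT1G56380 (0.50, adjusted p = 0.221) then did not pass, and the other named genes did. The count was 198 without yda11 replicate 1, 181 without yda11 replicate 3, 50 under quantile normalization, 19 without dim probe sets, 5 with array weights and 0 in the fit to these 6 arrays alone.

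After mock treatment at 1 dpi, the highest differences were those of plastid-encoded genes: psbC of photosystem II at 2.53 ± 0.47 (5.79-fold, adjusted p = 0.0207), the Rubisco large subunit gene rbcL at 1.99 ± 0.34, the ATP synthase genes atpH at 1.94 ± 0.35 and atpF at 1.61 ± 0.32, cemA at 1.66 ± 0.34, rpl16 at 1.03 ± 0.17 and petA at 0.99 ± 0.13. The median over the 43 plastid-encoded genes was 0.96, and 7 of them passed (camera adjusted p = 5.3e-43, and adjusted p = 0.210 with an estimated correlation). In the same comparison the 16 mitochondrial-encoded genes had a median of 0.18 (camera adjusted p = 0.00368, adjusted p = 0.425 with an estimated correlation, 0.105 without dim probe sets and 0.297 without the 3 arrays that stood apart). Without wild-type replicate 3, the array with low plastid values, the median of the plastid-encoded genes was 0.37 and 2 of them passed. Of the nuclear genes, AT4G14480 was higher by 1.04 ± 0.11 (adjusted p = 3.5e-05), AT1G11850 by 1.03 ± 0.17 and AT1G04800 by 1.00 ± 0.20. The heat shock list had 0 genes passing and 1 adjusted over the list alone (median 0.61, camera adjusted p = 0.00629, and adjusted p = 0.129 with an estimated correlation), with 1487 of all probe sets at an unadjusted p under 0.05 by limma. In total 24 probe sets were higher and 1 lower, and AT4G14480 and petA kept their calls without each array in turn. The count was 52 without wild-type replicate 2, 14 without wild-type replicate 3, 9 without yda11 replicate 2, 9 without yda11 replicate 3, 39 with array weights and 0 in the fit to these 6 arrays alone.

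**Figure D4:**
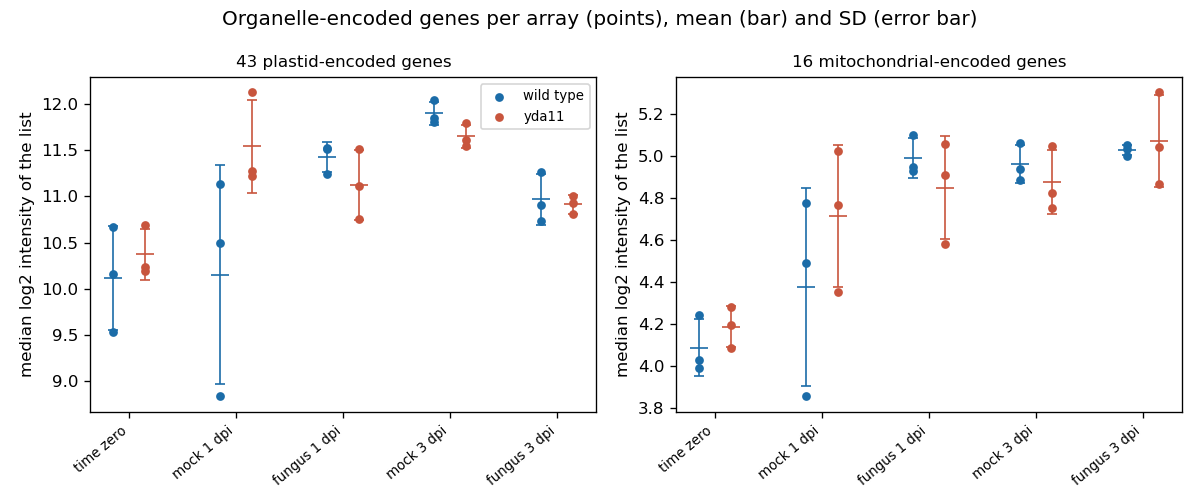
Median log2 intensity of 43 plastid-encoded and 16 mitochondrial-encoded genes on each array (points), with the group mean (bar) and SD (error bars). The wild-type array lowest in plastid-encoded genes, after mock treatment at 1 dpi, lies at 8.84 and is also the lowest in mitochondrial-encoded genes, at 3.85.

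After infection at 1 dpi, AT4G14480, the gene of the guard cell kinase BLUS1, was 2.31-fold higher in yda11 (1.21 ± 0.11, adjusted p = 1.8e-06). CHX20 (AT3G53720), a cation exchanger of guard cells, was higher by 0.84 ± 0.15 and CCS (AT1G12520), the copper chaperone of superoxide dismutase, by 0.55 ± 0.09. AT1G51915 (1.17 ± 0.20), AT2G21080 (0.85 ± 0.16), AT1G33811 (0.85 ± 0.14) and AT5G67340 (0.74 ± 0.13) were higher and AT5G48530 (-0.84 ± 0.16) lower, among 15 changed probe sets, 13 higher and 2 lower. CHX20 did not pass under quantile normalization (0.79, adjusted p = 0.0746) or median centring (0.78, adjusted p = 0.0842). AT4G14480 alone of the named genes kept its call without each array in turn. Of 4 abscisic acid response genes 0 passed and 2 adjusted over the list alone (median -0.35, camera adjusted p = 0.0355, adjusted p = 0.298 with an estimated correlation 0.055 under median centring and 0.0501 without the 3 arrays that stood apart). The count was 9 without wild-type replicate 1, 29 without yda11 replicate 1, 1 without yda11 replicate 2, 3 without yda11 replicate 3, 315 with array weights, 9 with a variance trend and robust settings and 1 in the fit to these 6 arrays. With the replicate number as a block it was 33. Of 7 pattern-triggered immunity genes 0 passed by limma, with an unadjusted p under 0.05 in 1447 of all probe sets, and 1 passed adjusted over the list alone (median 0.54, camera adjusted p = 0.000317, and adjusted p = 0.265 with an estimated correlation).

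After mock treatment at 3 dpi, AT2G43590 was 2.88-fold higher in yda11 (1.52 ± 0.29, adjusted p = 0.0424), AT1G51620 was higher by 1.17 ± 0.21, AT4G14480 by 1.10 ± 0.11 (adjusted p = 1.2e-05), AT1G68500 by 0.85 ± 0.14 and AT1G44760 by 0.55 ± 0.09. These 5 are among 10 changed probe sets, 9 higher and 1 lower. The secreted antimicrobial proteins tended higher, with 1 of 14 passing and 3 adjusted over the list alone (median 0.15, camera adjusted p = 0.00253, and adjusted p = 0.0469 with an estimated correlation). Of 7 pattern-triggered immunity genes 0 passed by limma, with 857 of all probe sets at an unadjusted p under 0.05, and 4 passed adjusted over the list alone (median 0.59, camera adjusted p = 0.000149, and adjusted p = 0.221 with an estimated correlation). AT4G14480 kept its call without each array in turn, and the other 4 lost it without at least 1 array. The count was 4, 5 and 4 without wild-type replicates 1, 2 and 3, 6 without yda11 replicate 2, 6 without yda11 replicate 3, 99 with array weights, 16 without the 3 arrays that stood apart and 2 in the fit to these 6 arrays. With the replicate number as a block it was 31.

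After infection at 3 dpi the genotypes differed in 119 probe sets, 97 higher and 22 lower in yda11. AT4G29780 was 9.09-fold higher (3.18 ± 0.64, adjusted p = 0.0193), AT3G02840 was higher by 2.22 ± 0.40 and WRKY53 (AT4G23810), a transcription factor of senescence and defence, by 2.08 ± 0.41. AT3G48650 (2.04 ± 0.38), AT5G05300 (2.03 ± 0.38), AT5G66650 (1.92 ± 0.26), AT1G58420 (1.85 ± 0.23), AT2G24160 (1.69 ± 0.39), the calmodulin-like gene CML37 (1.59 ± 0.29) and the acylhydrolase gene DLAH (1.58 ± 0.31) were higher too. QQS (AT3G30720), known for its effect on starch content, was 7.89-fold lower (-2.98 ± 0.62, adjusted p = 0.0235). AT3G46490 (-1.12 ± 0.24), AT1G22160 (-1.03 ± 0.24), the nitrate transporter gene NRT2.5 (-0.89 ± 0.19), P1R1 (-0.85 ± 0.18), AT1G78020 (-0.72 ± 0.13), AT5G39970 (-0.70 ± 0.15), AT3G13674 (-0.70 ± 0.14), AT2G02780 (-0.62 ± 0.13) and AT1G01940 (-0.51 ± 0.10) were also lower. AT5G66650 and AT1G58420 kept their calls without each array in turn, and the other 18 named genes lost theirs without at least 1 array. WRKY53, for example, was at 1.76 without wild-type replicate 2 (adjusted p = 0.178). The count was 33, 23 and 475 without wild-type replicates 1, 2 and 3, and 79, 76 and 26 without yda11 replicates 1, 2 and 3. It was 572 with array weights, 554 without the 3 arrays that stood apart and 0 in the fit to these 6 arrays.

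In this comparison the pattern-triggered immunity genes were higher as a group in yda11. WRKY53 passed among 7, and 5 passed adjusted over the list alone (median 0.80, camera adjusted p = 3.0e-09, and adjusted p = 0.0469 with an estimated correlation). PUB22 was at 1.00, WRKY6 at 0.80 and BIK1 at 0.53. Of 10 photosynthesis genes 0 passed by limma, with 1899 of all probe sets at an unadjusted p under 0.05, and 0 passed adjusted over the list alone (median -0.15, camera adjusted p = 0.0126, and adjusted p = 0.394 with an estimated correlation). That call was lost without the 3 arrays that stood apart (adjusted p = 0.136). Of the added families, 3 of 70 TIR-domain genes passed, among them AT1G57630 at 1.06 and AT5G58120 at 1.04 (camera adjusted p = 2.8e-05, and adjusted p = 0.291 with an estimated correlation).

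Whether yda11 responds to the fungus differently from wild type was tested as the difference between the infection responses. At 1 dpi, 0 probe sets passed by limma, 849 had an unadjusted p under 0.05 and the lowest adjusted p was 0.116, for an unnamed probe set (1.18 ± 0.20). The next lowest named genes were plastid-encoded: petA at -1.03 ± 0.19 (adjusted p = 0.120), atpH at -2.28 ± 0.49 and rpl16 at -1.05 ± 0.23 (0.443 each). Their contrast includes the wild-type mock array with low plastid values. The count was 15 without wild-type mock replicate 2, 6 without infected yda11 replicate 1, 3 without yda11 time-zero replicate 2, 1 without wild-type mock replicate 1 or infected wild-type replicate 2, 1 under median centring and 2 with array weights. With the replicate number as a block it was 1.

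At 3 dpi, 3 probe sets passed the test of the difference, and none of the 3 matches exactly 1 gene. Their differences were 1.48 ± 0.21 (adjusted p = 0.00759), 1.63 ± 0.27 and -0.82 ± 0.13 (adjusted p = 0.0198 for both). The count was 1 without wild-type mock replicate 2, wild-type mock replicate 3, yda11 mock replicate 3, infected yda11 replicate 1 or infected yda11 replicate 2, 1 without dim probe sets, 9 with array weights and 0 in the fit to the 12 arrays alone. AT1G58420 had a difference of 1.78 ± 0.33 that did not pass (adjusted p = 0.0986). The pattern-triggered immunity genes had a larger response in yda11 as a group (median 0.27, camera adjusted p = 0.0110, and adjusted p = 0.484 with an estimated correlation), with 0 of 7 members passing by limma, 718 of all probe sets at an unadjusted p under 0.05, and 0 passing adjusted over the list alone. Of the 97 probe sets that were higher in infected yda11 at 3 dpi, 1 passed the test of the difference of responses. WRKY53, at 1.00, did not pass it (adjusted p = 1.00).

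Because several probe sets recurred over the conditions, yda11 was also compared with wild type averaged over all 5, a comparison chosen after those values were seen. QQS was 5.27-fold lower in yda11 (-2.40 ± 0.28, adjusted p = 8.8e-06), and its difference ran from -1.48 after mock treatment at 1 dpi to -2.98 after infection at 3 dpi. It varied within wild type: replicate 1 lay at log2 6.52 at time zero against 9.39 and 9.51 on the other arrays, within the yda11 range of 5.95 to 6.96. Replicate 1 was also low after infection, at 6.96 against 9.18 and 9.14 at 1 dpi and 7.99 against 9.49 and 9.82 at 3 dpi. AT2G20670 was higher by 2.01 ± 0.52, AT3G10930 by 1.31 ± 0.25, the jasmonate-responsive transcription factor gene ORA47 by 1.28 ± 0.33, AT4G29780 by 1.21 ± 0.29 and the zinc finger gene STZ by 1.13 ± 0.27. AT1G25400 (1.08 ± 0.22), AT1G05575 (1.08 ± 0.17), AT4G27280 (1.03 ± 0.26), AT3G19030 (1.01 ± 0.19) and AT2G39690 (0.98 ± 0.11) were higher and AT2G47630 (-0.82 ± 0.11), AT4G01390 (-0.75 ± 0.15), AT3G46490 (-0.69 ± 0.11), the jacalin-like lectin gene JAL22 (-0.66 ± 0.12), AT4G02850 (-0.65 ± 0.10), AT3G15680 (-0.65 ± 0.10), AT1G14120 (-0.61 ± 0.12), AT2G47610 (-0.61 ± 0.08) and AT4G29030 (-0.58 ± 0.11) lower. Of these 20, 16 kept their calls without each array in turn, all but AT2G20670, ORA47, STZ and AT4G27280. In total 647 probe sets passed, 429 higher and 218 lower. The count was 1203 without infected wild-type replicate 3 at 3 dpi, 417 without infected wild-type replicate 2 at 3 dpi, 412 without infected yda11 replicate 2 at 1 dpi, 1254 with array weights and 1164 without the 3 arrays that stood apart. The share higher, 66.3%, was 55.2% under quantile normalization and 52.9% under median centring.

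Within single conditions, 16 probe sets passed in 2 or more of the 5, all in 1 direction, where 0.532 would if the calls were independent. The calls are not independent, since the comparisons share 1 estimate of the spread per probe set. AT4G14480 passed in all 5, at 0.71, 1.04, 1.21, 1.10 and 0.70 for time zero, mock and infected at 1 dpi, and mock and infected at 3 dpi, with a mean intensity of 45.1 in wild type at time zero. AT1G33811 passed in 4 and AT1G68500 in 3, and CHX20, AT3G20300 and CCS in 2. Some genes of the stomatal lineage and guard cells passed on average over the conditions. FMA, which acts in the last step of guard cell formation, was higher by 0.52 ± 0.09 (adjusted p = 0.00119), MUTE by 0.42 ± 0.11 (adjusted p = 0.0364) and the guard cell marker AT1G22690 by 0.58 ± 0.08 (adjusted p = 6.9e-05), whereas SPCH had 0.09 ± 0.10 (adjusted p = 0.731) and STOMAGEN -0.17 ± 0.08 (adjusted p = 0.321). The stomatal lineage list, with 2 of 4 passing and 2 adjusted over the list alone, did not pass as a set (camera adjusted p = 0.0769). AT1G22690 is the 1 measured gene of the guard cell list set before the data were examined, which does not hold AT4G14480 or CHX20. Of 7 pattern-triggered immunity genes 5 passed and 6 adjusted over the list alone, among them WRKY53 at 0.89, WRKY22 at 0.81 and PUB22 at 0.73 (camera adjusted p = 3.1e-07, and adjusted p = 0.114 with an estimated correlation). STZ of the oxidative stress list and COR15A of the abscisic acid list, at -0.46, passed in lists that did not (camera adjusted p = 0.0707 and 0.18).

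The last comparison set mock-treated plants of both genotypes against time zero, before the spray and the move to the warmer chamber, so that age, spray and chamber change together. At 1 dpi, AT1G30250 fell 65.6-fold (-6.04 ± 0.16, adjusted p = 2.35e-18), the dehydrin gene LTI30 by 4.80 ± 0.23 on the log2 scale, the thionin gene THI2.2 fell by 4.26 ± 0.24, the anthocyanin gene DFR by 3.83 ± 0.18 and COR15A by 3.81 ± 0.18. AT4G19430 rose by 5.09 ± 0.22, MSRB9, a methionine sulfoxide reductase gene, by 3.45 ± 0.18, the small heat-shock protein gene AT4G21870 by 3.34 ± 0.23, CYP71B22 by 3.05 ± 0.20 and BHLH101 by 2.75 ± 0.42. At 3 dpi, AT2G43620 rose 57.8-fold (5.85 ± 0.21, adjusted p = 4.65e-16), AT4G19430 by 4.76 ± 0.22, AT4G12500 by 4.74 ± 0.30, the peroxidase gene AT5G64120 by 4.22 ± 0.24 and CYP71B22 by 3.85 ± 0.20. AT1G30250 (-5.89 ± 0.16), THI2.2 (-4.69 ± 0.24), AT3G28220 (-3.99 ± 0.23), DFR (-3.77 ± 0.18) and the expansin gene EXPA16 (-3.40 ± 0.21) were lower. In mock-treated plants DFR lay under the bacterial control median of 6.62 on both days, so its falls are lower bounds. In total 7170 probe sets changed at 1 dpi, 3574 higher and 3596 lower, and 7141 at 3 dpi, 3486 higher and 3655 lower. Under median centring the median log2 fold change of all probe sets was -0.15 at 1 dpi and -0.124 at 3 dpi, against -0.0501 and -0.056 without it, and 26.2% and 33.1% of the changed probe sets were higher in place of 49.8% and 48.8%, and the count at 1 dpi was 4662 in the fit to the arrays of the comparison alone. The 20 genes named here kept their calls without each array in turn.

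Genes of abscisic acid response fell in these mock-treated plants, 3 of 4 on each day and also when adjusted over the list alone (camera adjusted p = 0.000271 and 0.00428, and adjusted p = 0.0597 and 0.134 with an estimated correlation). Of 7 pattern-triggered immunity genes, 6 rose at 3 dpi, and 6 adjusted over the list alone, with PUB22 at 1.34 and WRKY53 at 1.25 (camera adjusted p = 0.00137, and adjusted p = 0.331 with an estimated correlation). Plastid-encoded genes rose at 3 dpi in 37 of 43 (median 1.30, camera adjusted p = 9.3e-19, and adjusted p = 0.320 with an estimated correlation), and mitochondrial-encoded genes in 11 of 16 (median 1.25, camera adjusted p = 2.8e-07, and adjusted p = 0.221 with an estimated correlation). The guard cell marker AT1G22690 rose by 0.90 and 1.13 and the sucrose exporter gene SWEET11 by 0.86 and 0.75 at 1 and 3 dpi. The wax ester gene WSD1 fell by 0.78 and 0.83, and BCAT4 of aliphatic glucosinolate synthesis by 1.05 and 0.88.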

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

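The tests of explanations in this part were chosen after the result was seen, and so were the splits for the average over the 5 conditions, but not the test of RNA integrity and the other splits of the arrays.

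The infection response differed between the days in 338 probe sets in wild type and 390 in yda11, by a test of the difference. In wild type the difference was 5.06 for JRG21, 4.69 for OSM34, 3.78 for AT3G55790, 3.64 for AT5G39520 and 3.39 for AT2G37750, and for plastid-encoded genes -4.73 (psaA), -3.36 (psbC), -3.33 (ycf4), -2.94 (atpH) and -2.94 (atpI). In yda11 it was 4.56 for JRG21, 4.47 for OSM34, 4.03 for AT1G09500, 3.88 for AT5G39520 and 3.80 for AT3G55790, and -3.84 for AT2G43620, -2.30 for AT4G36700, -2.26 for UGT76B1, -2.11 for AT1G56060 and -1.93 for AT5G48540. Of 100 splits of the 12 arrays, 8 gave as many probe sets in wild type (highest 3569) and 7 in yda11 (highest 3033), so these splits do not exclude chance for the counts. They swap the days within mock and within infected arrays, so effects of day that both share enter the swapped contrast, and splits with several times the real count point to that kind of structure of the samples. JRG21 and OSM34 kept their calls without each array in turn in both genotypes.

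Lists also differed between the days, but no such camera call held with an estimated correlation. Tryptophan-derived defence metabolism responded less at 3 dpi in wild type (adjusted p = 0.0126, and adjusted p = 0.146 with an estimated correlation; 1 of 3 passed and 2 adjusted over the list alone) and in yda11 (0.0315 and 0.221; 1 of 3, and 1 adjusted over the list alone). ATG8 autophagy genes had 0.000331 (0.429 with an estimated correlation) in wild type and 0.00425 (0.627) in yda11, chlorophyll biosynthesis 0.0264 (0.558) and 0.0252 (0.548). In wild type, class III peroxidases had 0.00285 (0.291) and plastid-encoded genes 1.9e-35 (0.221). In yda11, expansins had 0.0384 (0.291) and serine carboxypeptidase-like genes 0.0479 (0.419). Without the 3 arrays that stood apart the calls of tryptophan-derived metabolism in yda11 (0.0524), chlorophyll biosynthesis (0.061) and ATG8 genes (0.0757) in wild type and serine carboxypeptidase-like genes (0.0513) were lost. Without dim probe sets those of tryptophan-derived metabolism (0.0535) and chlorophyll biosynthesis (0.0535) in yda11 were, and under quantile normalization that of chlorophyll biosynthesis in wild type (0.0782).

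Between the genotypes, 3 probe sets differed in infection response at 3 dpi, at 1.48, 1.63 and -0.82, and as large a count came from 11 of 100 splits (highest 221). These splits do not exclude chance for the count. They swap the genotypes within mock and within infected arrays, so genotype differences that both share enter the swapped contrast. They are therefore no clean test of chance. At 1 dpi 0 probe sets passed by limma, with 849 at an unadjusted p under 0.05. Every split reaches a count of 0, so the 100 splits (highest 62) cannot test it. Lists that differed at 3 dpi were pattern-triggered immunity (adjusted p = 0.0110, and 0.484 with an estimated correlation), TIR-domain genes (0.00285 and 0.479), berberine bridge enzyme-like oxidases (0.0360 and 0.627) and calmodulin-like genes (0.0209 and 0.330). At 1 dpi they were plastid-encoded genes (2.8e-41 and 0.210), mitochondrial-encoded genes (0.0301 and 0.641), tetraspanins (0.0105 and 0.210) and calmodulin-like genes (0.0211 and 0.330). Median centring ended the call of the oxidases (0.0747). The mitochondrial call was lost without dim probe sets (0.214), under median centring (0.088) and without the 3 arrays that stood apart (0.441), that of tetraspanins without dim probe sets (0.108) and that of calmodulin-like genes at 1 dpi without the 3 arrays (0.0609).

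Outside the comparisons, some of the 64 control probe sets were higher after infection, although they are not part of the genes tested: 4 in wild type at 1 dpi, 2 in wild type at 3 dpi, 5 in yda11 at 1 dpi and 5 in yda11 at 3 dpi, among them probe sets for ubiquitin and GAPDH transcripts of the plant.

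After mock treatment at 1 dpi, plastid-encoded genes were higher in yda11, with a median of 0.957 over 43 genes. A lasting genotype difference of that size is argued against, since the median was under 0 in 3 of the other 4 conditions (0.143, -0.131, -0.134 and -0.0442). A share of organelle RNA that differs between arrays of one group may explain it: plastid and mitochondrial deviations from the group means correlated over 30 arrays (r = 0.8, permutation p = 0.011 and adjusted p = 0.033 over 3 relations, rho = 0.488, permutation p = 0.0438 before adjustment). The lowest and highest plastid median deviations, -0.790 and 0.905, were both on wild-type arrays after mock treatment at 1 dpi. The pattern rests on these arrays, so the correlation is no independent test. Without the 2 farthest arrays r was 0.543, for which no p was computed. Without the low wild-type array the median was 0.367 with an SE of 0.442, which leaves that explanation open, as does r = 0.0409 with the GAPDH 3' minus 5' difference (permutation p = 0.871) for RNA integrity. The splits of 6 arrays are too few for a share under 0.05 (real 25, highest other 15, 1 of 10 as large).

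The 97 probe sets higher in infected yda11 at 3 dpi had a median difference of 1.14, which their selection raises, and of 0.348 after mock treatment at 3 dpi, where 87 were positive. A genotype difference of the same size without infection stays open, since 1 of the 97 passed the test of the difference between the responses. A stronger infection response as a whole in yda11 stays open as well: the 100 genes most induced in wild type at 1 dpi had a median difference of responses of 0.176 (quartiles -0.0575 and 0.454), with a genotype difference of 0.448 after infection and 0.303 after mock treatment. The part of one array stays open, with counts of 33, 23 and 475 without wild-type replicates 1, 2 and 3 and 79, 76 and 26 without yda11 replicates 1, 2 and 3. The splits are too few for a share under 0.05 (real 119, highest other 239, 3 of 10 as large).

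Some probe sets differed in yda11 in several conditions. Without the time-zero array of raised background (bacterial control median 11.9), 18 passed in 2 or more of the 4 later conditions in 1 direction. If the calls were independent 0.591 would, but the comparisons share 1 estimate of the spread per probe set. That array enters these 4 comparisons only through this spread. The raised background of one time-zero array is therefore argued against for them by the design, and the count is no test of it. More stomatal-lineage and guard cells in yda11 stay open: of 5 measured genes of the stomatal lineage and guard cell lists 3 were higher on average (FMA 0.524, AT1G22690 0.583 and MUTE 0.42, which was dim), SPCH was at 0.0941 and STOMAGEN at -0.171, and the stomatal lineage list did not pass (camera adjusted p = 0.0769). Neighbouring genes that change together stay open, with 11 neighbouring pairs among 325 genes against a median of 4 in 10000 random draws (permutation p = 0.006), since as many genes of the infection response had 20 (permutation p = 1e-04, the smallest the draws can give). The 647 probe sets of the average exceeded the highest other split, 17, and 1 of 100 splits gave as many, the smallest share these splits can give. The splits argue against chance for that count, but the comparison was chosen from the same arrays and the splits leave the replicate numbers out of account.

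For the infection comparisons the splits of 6 arrays are too few for a share under 0.05, with 1 of 10 as large in each: the real counts were 6859, 6943, 7214 and 7729 and the highest others 0, 1, 0 and 1. The same holds for yda11 against wild type at time zero (real 32, highest other 183, 7 of 10 as large), after infection at 1 dpi (15, 11 and 1) and after mock treatment at 3 dpi (10, 4 and 1). For mock-treated plants against time zero 1 of 100 splits was as large at 1 dpi (real 7170, highest other 2786) and 1 at 3 dpi (real 7141, highest other 3037). That is the smallest share these splits can give, and 51 and 28 of the other splits also called probe sets. The splits argue against chance for these counts but leave the replicate numbers out of account.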

How the results depend on the processing

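Leaving out the 3 arrays that stood apart was chosen after the values were seen. The infected wild-type replicate 3 at 3 dpi was picked partly from the pattern it affects. The wild-type mock replicate 3 at 1 dpi was picked for its low plastid values, while its mean correlation with its own group was 0.993. Plastid and mitochondrial calls lost without the 3 arrays are therefore no independent check. Where a count below differs from the reported one, the cause was not tested, except that a minimum change lowers counts by construction and 1 probe set per gene leaves fewer to count. With the replicate number as a block the count of changed probe sets was 33 for yda11 against wild type after infection at 1 dpi, 31 after mock treatment at 3 dpi, 1 for the difference in response at 1 dpi, 174 after infection at 3 dpi and 879 for the average, and the call of photosynthesis genes in infected yda11 at 1 dpi was lost (adjusted p = 0.0519). Deviations of arrays of the same number had a mean r of 0.0791 over 135 pairs, from -0.316 to 0.639 and over 0.1 in 55. For other numbers it was -0.0394, which largely follows from the first value, since deviations sum to 0 within a group. Of 30 arrays, 25 correlated best with their own number, a hint from the data and not from the design that numbers share something, which neither the reported fits nor the splits take into account. In the fit to the arrays of each comparison alone the counts were 0 at time zero, 0 after mock treatment at 1 dpi, 1 after infection at 1 dpi, 2 after mock treatment at 3 dpi, 0 after infection at 3 dpi, 0 for the difference in response at 3 dpi and 4662 for mock treatment against time zero at 1 dpi. Without dim probe sets they were 19 at time zero and 1 for the difference at 3 dpi. Quantile normalization gave 50 at time zero, median centring 1 for the difference at 1 dpi, and a variance trend with robust settings 9 after infection at 1 dpi.

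With array weights, yda11 against wild type gave 5, 39, 315, 99 and 572 at time zero, mock and infected at 1 dpi, and mock and infected at 3 dpi, 2 and 9 for the differences in response, 933 and 722 for the differences between days and 1254 for the average. A minimum of 2-fold left 1893, 2024, 2275 and 2538 for infection in wild type and yda11, 9, 11, 5, 4 and 72 for the genotypes, 642 and 874 for mock treatment against time zero and 21 for the average. With 1 probe set per gene these were 3557, 3477, 3635 and 3962, then 14, 16, 7, 5 and 47, 0 for the difference at 3 dpi, 169 and 162 between days, 3998 and 3852 against time zero and 283 for the average. Without the 3 arrays that stood apart the counts were 16 after mock treatment at 3 dpi, 554 after infection at 3 dpi and 1164 for the average.

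Leaving out each array in turn, the counts ranged from 5626 to 7176 and 5544 to 7250 for infection in wild type at 1 and 3 dpi, and from 6006 to 7530 and 6440 to 8179 in yda11. For the genotypes they ranged from 28 to 198 at time zero, 9 to 52 and 1 to 29 after mock and infection at 1 dpi, and 4 to 14 and 23 to 475 at 3 dpi. Differences in response ran from 0 to 15 and 1 to 4, differences between days from 252 to 401 and 287 to 463, mock treatment against time zero from 5939 to 8130 and 6182 to 7974, and the average from 412 to 1203.

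Of 395 called values of named genes, 393 kept their call with the block, 382 under quantile normalization, 383 under median centring, 387 with the variance trend, 379 with array weights and 362 without the arrays that stood apart, 287 of 365 kept it in the arrays of the comparison alone, and 311 kept it without each array in turn. None reversed in these settings. Of 36 list calls, 35 were kept with the block, 35 under quantile normalization, 35 under median centring, 29 without dim probe sets, 33 without the arrays that stood apart, and 10 with an estimated correlation, while fry made 57 calls. Signal over background limits dim probe sets: the median intensity over all arrays was 54.0 and the bacterial controls lay at 6.62.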

Other observations

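Among the genes that respond to the fungus in both genotypes are some of secreted defence (PDF1.2, CHI and OSM34), of tryptophan-derived metabolites (AT2G04400 and CYP71B6) and of the berberine bridge enzyme-like oxidases (AT1G26380 and AT1G26390), and COR15A among those that fell. Between the genotypes, AT4G14480 and QQS, a guard cell kinase gene and an orphan gene, hold the same sign in all 5 conditions, the first at 0.70 to 1.21 and QQS at -2.98 to -1.48. AT4G14480 passed in all 5, and QQS in 1 of them, where it lost its call without at least 1 array.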
